A study of Mus musculus with 2 samples.

How the data were processed

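Messenger RNA levels were measured on single-colour arrays in mouse embryonic fibroblasts labelled as Xbp1 knockout, with 1 culture sample on day 0 and 1 on day 3 of induced adipogenesis. Per the labels' protocols, total RNA was extracted with a column kit, and 1 µg was amplified and labelled by the array company Phalanx. The dye was Cy5 on both arrays. The groups were taken from the stage given in the labels.

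The deposited per-sample tables gave 1 linear fluorescence intensity for each of 39200 spots per array. Background appeared to be subtracted already, because the 7402 spots named as empty had a median intensity of 0 on both days and a 95th percentile of 7 on day 0 and 9 on day 3. The scanner, the image software and the background method are not given in the sources used here. The authors' table for the whole series held intensity values for 11482 of 29922 gene probes, by a rule that was not given. Within each day its probes had the same rank order as in the per-sample table, and 99.8% of its sorted values differed by less than 1% between the days, as quantile-normalized values do. The column medians were 1414 on both days, on a linear scale. Of the probes above the detection threshold on both days, 2303 had no value in the authors' table, and of the 2462 above it on 1 day only, 88 had a value. The per-sample intensities were therefore used for the main results and the authors' table for an alternative.

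The 29922 gene probes were quantile normalized between the arrays with limma 3.58.1 in R 4.3.3. Signals under 10 were then set to 10, and log2 was taken. No further background was subtracted. A gene was called detected where its signal exceeded the median of all gene probes, 122 (6.93 on the log2 scale), on at least 1 day. This fallback had been fixed for files with neither detection flags nor probes named as negative controls. Because it is the median of the gene probes, about as many probes fall under it as over it whatever the number of expressed genes. Signals of 65000 or more were treated as saturated.

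Probe names came from the platform annotation supplied with the series and were updated through a gene table of assembly GRCm38.p6. Exactly 1 symbol was given for 21020 probes and none for 8902, and 0 probes had several. Of the symbols, 17558 were current, 3410 were matched as synonyms and 52 were kept as given. An older name in a gene list was ignored where the table assigns it to another gene. The named probes represented 16637 genes, 3566 of them with more than 1 probe, and the probe with the highest mean log2 signal stood for its gene. Neither probe sequences nor probe positions were analysed here.

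The comparison was the log2 difference of normalized signals, day 3 minus day 0, and genes with a difference of at least 2-fold were counted. These counts use signals down to the floor of 10, so a gene below the threshold on 1 day can be counted although its lower bound is under 2-fold, and counts at the bound are given where they differ. With 1 sample per group there was no test and no p-value. Where a signal lay below the threshold or was saturated on 1 day, the fold is given as a lower bound, computed against the threshold or the saturated value. No fold is given where both days were below the threshold. Control features printed as 5 or 6 spots gave a technical error: the SD of a difference between days, from the median SD of repeated spots, was 0.43 for log2 signals of 6 to 8, 0.54 for 8 to 10, 0.40 for 10 to 12 and 0.38 for 12 to 16. Pooled over the features instead, which weighs the noisier ones more, it was 0.60, 0.85, 0.57 and 0.88. It covers scatter between spots and leaves out variation between cultures, RNA extractions and hybridizations. For arrays, the number of samples limits the precision.

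The median difference of each gene list was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes these arrays and is no p-value. A list is called outside the random range where its median lay beyond the central 95%, from the 2.5th to the 97.5th percentile. The 23 gene lists, the 8 sets of markers of other cell types, the fold threshold and the alternatives were chosen before the data were examined, except 3 alternatives and 4 lists named below as added. Genes were named by a rule fixed at the same time: 11 regulators and markers whatever their values, the 10 largest differences in each direction among detected genes whose mean log2 signal was above the median of detected genes, 10.0, and whose direction held under every normalization, and up to 4 members of each list with the largest differences. Applied also to the 4 lists added after the data were seen, the rule named 151 genes, 1 of which, Cebpd, was not on the array under that symbol. Any gene named outside this rule is marked as such.

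The alternatives were median scaling over all gene probes, cyclic loess with 3 iterations, no normalization, an added offset of 50, no detection filter, a filter on both days above the median of detected probes, the mean of all probes of a gene, the authors' table, fold thresholds of 1.5 and 3, and random lists not matched on signal. Added after the data were seen were a floor at the detection threshold, median scaling over probes detected on both days, and a filter on mean signal above the median of detected genes. Alternatives used 2000 random lists.

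The code was tested on simulated data with 15404 probes, a noise SD of 0.4 on the log2 difference and 200 changed probes. For the day 3 against day 0 comparison it recovered 100% of probes with a planted log2 difference of 2 or -2 as at least 2-fold, 90% at 1.5 and 88% at -1.5, and called 1.09% of unchanged probes. A planted list reached percentile 100, and 5 of 100 unchanged lists fell outside the central 95%. The simulated noise was below every pooled repeat-spot SD given above and held no variation between cultures or hybridizations. Changes were planted only in probes that were neither among the dimmest nor among the brightest. These rates therefore check the code and are no error rates for the 2 arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.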

Results

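Gene expression was compared between day 0 and day 3 of drug-induced adipogenesis, the formation of fat cells, in mouse embryonic fibroblasts labelled as knockout for Xbp1. Xbp1 encodes a transcription factor of the unfolded protein response, the programme that cells mount when unfolded protein builds up in the endoplasmic reticulum (ER). Day 0 was the day of confluence. Induction lasted 72 h in medium with 10 µg/ml insulin, 5 µM troglitazone, which is an agonist of PPARγ, 5 µM DXM and 0.25 mM IBMX, which inhibits the phosphodiesterases that break down cAMP. The question set by the design was how expression on day 3 stood against day 0 in these cells, and cells with intact Xbp1 were not analysed here. Each day was 1 array, so no difference below has a replicate check and no p-value was computed. The median raw intensity of the gene probes was 78 on day 0 and 166 on day 3, against a median of 0 for empty spots on both days. Of 16637 genes on the array, 10656 were detected on at least 1 day and 9434 on both. Day 0 and day 3 signals correlated with Pearson's r of 0.919 and Spearman's rho of 0.926 across detected genes, which are not independent replicates.

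The signal of Xbp1 itself (probe mMC022331) was 20936 on day 0 and 13561 on day 3, a log2 difference of -0.63 against a repeat-spot SD of 0.38 from the median of repeated features and 0.88 when pooled over them, so it lies within the pooled error. Where this probe lies relative to the deleted part of the gene is not given in the sources used here, so its signal does not check the knockout label.

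The median differences of the lists of lipid catabolism, cAMP-responsive, basement membrane, and NRF2 and glutathione genes lay above the central 95% of matched random lists, toward day 3, with members on both sides of 0 in each. The cAMP list did so in every setting but 1. The medians for DNA replication, mitosis, the contractile cytoskeleton and the PERK and ATF4 branch of the stress response lay below it, toward day 0. Lpl, the lipase that releases fatty acids from circulating lipoproteins, was at least 6.99-fold higher, and the inhibitory kinase Pdk4 was 11.7-fold higher. Pparg, the nuclear receptor at the centre of adipocyte differentiation, differed by -0.71 on the log2 scale, within the pooled repeat-spot SD of 0.85. The fat cell products Fabp4 and Adipoq stayed below the detection threshold on both days in the main setting. On day 3 their raw intensities of 90 and 164 exceeded the 95th percentile of empty spots, 9, as did 89.3% of gene probes. In all, 1360 genes (12.8% of those detected) were at least 2-fold higher on day 3 and 1093 (10.3%) were at least 2-fold lower, while 54.8% differed by less than 1.5-fold. Those counts take signals below the threshold as read: 952 of the higher and 795 of the lower genes were above the threshold on both days, and 1091 were higher and 907 lower with every signal under the threshold set to it, a setting added after the data were seen.

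The share of genes higher or lower depended on how the arrays were put on a common scale. Higher genes made up 55.4% of the 2-fold genes in the main setting. That share was 24.3% (829 higher, 2586 lower) under median scaling over all gene probes, where the median difference of all detected genes was -0.49. It was 92.6% (3939 higher, 315 lower) with no normalization, where the median of all genes was 0.67, and 66.4% (1891 higher, 957 lower) under median scaling over probes detected on both days, which was added after the data were seen. Once the shift of the median of all genes was removed, higher genes made up 62.0% (1665 higher, 1020 lower), 63.0% (1874 and 1101) and 62.2% (1756 and 1065) in those 3 settings. The 3 differ from each other by 1 constant per array, which this removal takes out. Apart from the floor and the detection filter they are therefore the same setting, and their closeness is no separate check. Under cyclic loess the share was 49.1% (1221 higher, 1267 lower) as read and 52.6% (1312 and 1180) with the shift removed. Olfactory, vomeronasal, taste and trace amine receptor genes, a set examined after Olfr275 was seen among the largest differences, were 2-fold higher on day 3 in 78 of 126 detected cases, against 26.7 expected from other genes of the same mean signal, and 2-fold lower in 4, against 23.5 expected. With signals under the threshold set to it, 39 were 2-fold higher, against 10.95 expected, and 0 were 2-fold lower, against 9.48. Of the 126, 123 lay among the 5328 dimmer detected genes by mean signal, and 77 of these 123 were 2-fold higher. Of the other 3, 1 was 2-fold higher, and 3 genes are too few to judge bright genes by. Of all 5328 dimmer genes 923 were 2-fold higher and 695 lower, and of the 5328 brighter genes 437 were higher and 398 lower.

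Regulators of adipogenesis did not stand apart as a group. Of 15 detected adipogenic transcription factors, 2 were 2-fold higher on day 3, 1 of them also at its bound, and 5 were 2-fold lower, and the list's median of -0.10 lay at percentile 27.5 of matched random lists. In the authors' table the median was -0.55, outside the random range at percentile 1.60. The glucocorticoid receptor gene Nr3c1 (-2.56) and the early regulators Egr2 (-2.27), Klf5 (-1.70) and Klf4 (-1.68) had the largest differences, all toward day 0. The other detected probes of Klf4 gave -0.09 and -0.64. Cebpb was higher on day 3, with signals of 23631 and 38177.5 (0.69, within the pooled repeat-spot SD of 0.88), Pparg gave 608 and 372.5, and Cebpa gave 207.5 and 199, a difference of -0.06 that was smaller than the repeat-spot SD of 0.43.

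Of 22 adipocyte marker genes on the array, 13 were detected, 4 of them were 2-fold higher on day 3 and 0 were 2-fold lower. Those 4 act in lipid and glycerol handling: Lpl (2.83 by its other probe), the lipase genes Lipe (1.66) and Pnpla2 (1.25), and Aqp7, a glycerol channel gene that was below the threshold on day 0 and at least 2.21-fold higher on day 3. The median of the list, 0.17, lay inside the random range at percentile 70.4, and it was 0.07 with signals under the threshold set to it. Relative to all genes it was 0.68 (percentile 96.4) under median scaling over all gene probes, 0.69 (95.1) with no normalization and 0.72 (97.25) under the added scaling over probes detected on both days. It was below 0 in the authors' table (-0.15, 8 genes) and under both filters on brighter genes (-0.14, 5 genes). The other 9 marker genes stayed below the threshold of 122 on both days. Signals on day 0 and day 3 were 10.5 and 59.5 for Fabp4, 12 and 120.5 for Adipoq, 12 and 52.5 for Cidec, 21.5 and 44 for Plin1 and 15.5 and 10 for Cfd, and Lep, Cd36, Pck1 and Car3 read no more than 34.5 on either day. Of these, all but Fabp4 and Adipoq lie outside the naming rule and were chosen after their values were seen. Adipoq was detected on day 3 in 2 other settings: with no normalization (10 and 164, threshold 118) and under the added median scaling over probes detected on both days (10 and 138, threshold 117). Gapdh, a gene active in nearly all cells and likewise chosen after its values were seen, was also below the threshold (10 and 19.5), so a dim probe here does not show that its gene was silent.

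**Figure D1:**
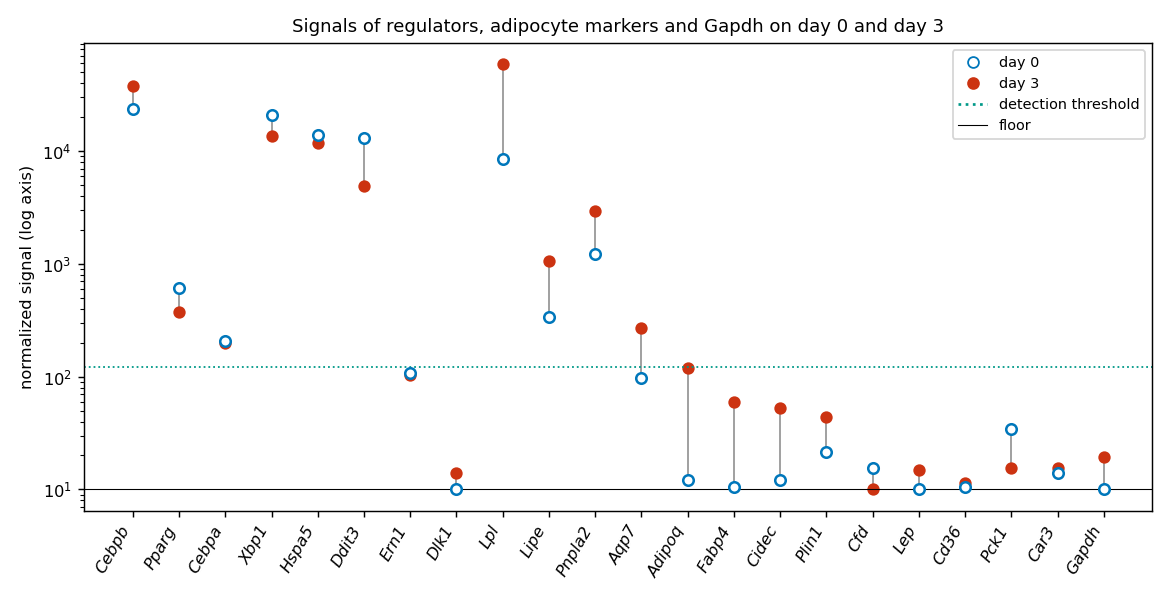
Normalized signals (log axis) of regulators, adipocyte markers and Gapdh on day 0 (open circles) and day 3 (filled circles), 1 array per day, with the detection threshold of 122 (dotted line) and the floor of 10 (solid line). Lpl, Lipe, Pnpla2 and Aqp7 lie higher on day 3 and above the threshold, while Adipoq (120.5 on day 3) and Fabp4 (59.5) lie below it on both days.

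Genes of lipid oxidation that respond to PPAR receptors stood highest among the lipid lists. Of 18 detected members, 10 were 2-fold higher on day 3 and 2 were 2-fold lower, and the median of 1.10 exceeded those of all matched random lists (percentile 100). Pdk4 (3.55), which restrains glucose oxidation, the lipase inhibitor gene Angptl4 (2.10) and Cpt1a (1.77), whose product admits fatty acids to mitochondria, were higher, and the fatty acid carrier gene Fabp3 (-1.72) was lower. The other detected probes of Angptl4 gave -0.69 and 1.497. Among 16 genes of fatty acid and triglyceride synthesis, 3 were 2-fold higher, namely Acacb (1.63), Lpin1 (1.33) and Elovl6 (1.01), and Gpam (-1.32) was lower. Their median of 0.41 lay at percentile 98.1, and it lay inside the random range under median scaling over all probes (percentile 97.1), with no normalization (96.6), under the added scaling over probes detected on both days (96.95) and against random lists not matched on signal (94.7). Cholesterol synthesis genes did not stand apart (median 0.17, percentile 77.7, 2 of 16 higher), and both higher members had probes at odds: Insig1 gave 1.97 by its brightest probe and -1.01 and -1.31 by the others, and Lss gave 1.77 and 0.02.

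Targets of cAMP signalling showed the largest median of any list in the main setting. Of 14 detected members, 9 were 2-fold higher on day 3, 0 were 2-fold lower, and the median was 1.86 (percentile 100). Dio2, which encodes the enzyme that activates thyroid hormone, was at least 19.9-fold higher, the orphan nuclear receptor gene Nr4a1 was 9.45-fold higher, the regulator of G protein signalling gene Rgs2 was 7.79-fold higher and the cAMP phosphodiesterase gene Pde4b was 7.65-fold higher. Of the 9, 3 were below the threshold on day 0. With such genes at their bound 7 were 2-fold higher and the median was 1.10. Under the filter that required both days to exceed the median of detected probes, 5 members remained and their median was -0.013, inside the random range. Glucocorticoid-responsive genes were 2-fold higher in 5 of 19 cases and lower in 0, with a median of 0.15 inside the random range (percentile 81.6). Of the 19, 13 differed by less than 1.5-fold, and 2 of these 13 were saturated on both days and could show no difference. Fkbp5 (1.85) and Per1 (at least 2.76-fold) were among the 5, as were Rgs2 and Angptl4, which other lists also hold. The median of this list was -0.038 relative to all genes with no normalization.

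Proliferation genes were lower on day 3. Of 27 detected DNA replication genes, 15 were 2-fold lower and 1 was 2-fold higher (median -1.03, percentile 0), and all 21 detected cell cycle and mitosis genes were lower, 8 of them 2-fold (median -0.81, percentile 0). The helicase subunit genes Mcm3 (-2.29) and Mcm6 (-1.89), the S-phase cyclin gene Ccne2 (-2.27) and Rrm2 (-2.06), a subunit of the enzyme that makes deoxyribonucleotides, had the largest differences of the replication list. Cdca8 (-1.73), Ccna2 (-1.41), Birc5 (-1.29) and Kif23 (-1.29) led the mitotic list. The other detected probes of Ccne2 (-2.09), Rrm2 (-2.11) and Birc5 (-1.44 and -2.07) gave the same direction. Both medians lay below the random range under every setting tried.

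Contractile genes were lower as a list, with 8 of 18 members 2-fold lower, 7 of them also at their bound, and 3 2-fold higher on day 3 (median -0.94, percentile 0). Ankrd1 was 12.1-fold lower, the smooth muscle actin gene Actg2 4.65-fold, the myosin light chain gene Myl9 3.57-fold and Tagln at least 1.74-fold. The 3 higher members, all also 2-fold at their bound, were Cnn1, which was below the threshold on day 0, Des (1.23) and Myh11 (1.11). These 3 lie outside the naming rule and were chosen after their values were seen. Matrix genes went the other way in part. Of 17 basement membrane genes, 4 were 2-fold higher as read and 0 were 2-fold lower (median 0.85, percentile 99.97). That median was 0.50 under both filters on brighter genes, with 10 members left and percentiles of 97.55 and 97.95, 0.53 in the authors' table (99.0) and 0.60 with the mean of all probes (99.5). Only 2 of the 4 were 2-fold at their bound, Col18a1 (1.72) and the laminin gene Lamb1 (1.48), because Col15a1 (at least 1.39-fold) and Sparcl1 (at least 1.74-fold) were below the threshold on day 0. Fibrillar collagens and other fibroblast matrix genes stayed inside the random range (median 0.20, percentile 93.1), with 5 of 24 higher and 2 lower, and their median was below 0, relative to all genes, under both median scalings and with no normalization. Postn (2.27), Fn1 (2.06) and Col6a3 (at least 3.39-fold, saturated on day 3, with 0.65 and 0.80 by its other probes) were higher and Thbs1 was 12.7-fold lower (-3.67, and -3.13 by its other probe).

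The unfolded protein response was covered by 3 lists. Of 17 detected PERK and ATF4 response genes, 6 were 2-fold lower on day 3 and 1 was 2-fold higher, and the median of -0.74 lay at percentile 0.01. The pseudokinase gene Trib3 (-1.84), the transcription factor gene Ddit3 (-1.41, from 13007.5 to 4885.5), the amino acid transporter gene Slc7a5 (-1.32) and Herpud1 (-1.16) were lower. Among 28 detected XBP1 and ATF6 target genes of ER folding, transport and degradation, 2 were 2-fold lower, Herpud1 and Sdf2l1 (-1.08), and 0 were higher. The median of this list was -0.15, inside the random range at percentile 13.7. The chaperone gene Hspa5 differed by -0.25, less than its repeat-spot SD of 0.38. The difference between the lists was not tested. Of 11 detected genes in the list of sensors and related factors, Mbtps2, a protease that processes ATF6, was the only 2-fold case (-2.42, and -2.51 by its other probe), and the list median was -0.19 (percentile 21.4). Among the sensors, Eif2ak3, which encodes PERK, differed by 0.55, and Atf6 was below the threshold on both days (49.5 and 35). These genes lie outside the naming rule and were chosen after their values were seen. Ern1, which encodes the sensor IRE1α, was below the threshold on both days (108 and 103), and it was detected on day 3 with no normalization (69 and 140, threshold 118) and under the added median scaling over probes detected on both days (84.9 and 117.9, threshold 116.9).

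NRF2 and glutathione genes had a median of 0.56 (percentile 99.8), with 4 of 17 members 2-fold higher, including Cat (1.84), Gsr (1.22) and Gsta4 (1.13), and 2 2-fold lower, including the haem oxygenase gene Hmox1 (-2.03). Inflammatory cytokine and chemokine genes went both ways. Cxcl2 (2.82) and Il6 (2.77) were higher, Ccl7 (-2.92) and Ccl20 (at least 3.68-fold) were lower, and 3 of 19 were 2-fold higher against 5 lower (median -0.08, percentile 28.2, with 3 of the 19 saturated on both days). That median was -0.45 relative to all genes, and outside the random range at percentile 2.25, under median scaling over all probes, and -0.44 at percentile 2.35 with no normalization. Interferon response genes, with Cxcl10 at -1.83, had 2 of 18 higher, 0 of them at their bound, and 2 lower (median -0.30, percentile 7.99, -0.20 at the bounds and 0.10 in the authors' table). The remaining fixed lists stood inside the random range: preadipocyte and anti-adipogenic factors (0.32, with a mean of -0.01, 2 of 14 lower, Dlk1 below the threshold), mitochondrial respiratory chain and TCA cycle genes (-0.01, with 0 of 30 at 2-fold), thermogenic genes (-0.02, with a mean of 1.22 owing to Dio2, 1 of 5 higher), heat shock genes (0.25, 1 of 9 lower) and reference genes (-0.26, with a mean of 0.00, 0 of 10 at 2-fold). The single 2-fold heat shock gene, Hsp90aa1, gave -1.06 and 0.07 by its other probe. Among the 30 lists and marker sets with a median, 9 lay outside the random range, and lists that share members are not independent.

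**Figure D2:**
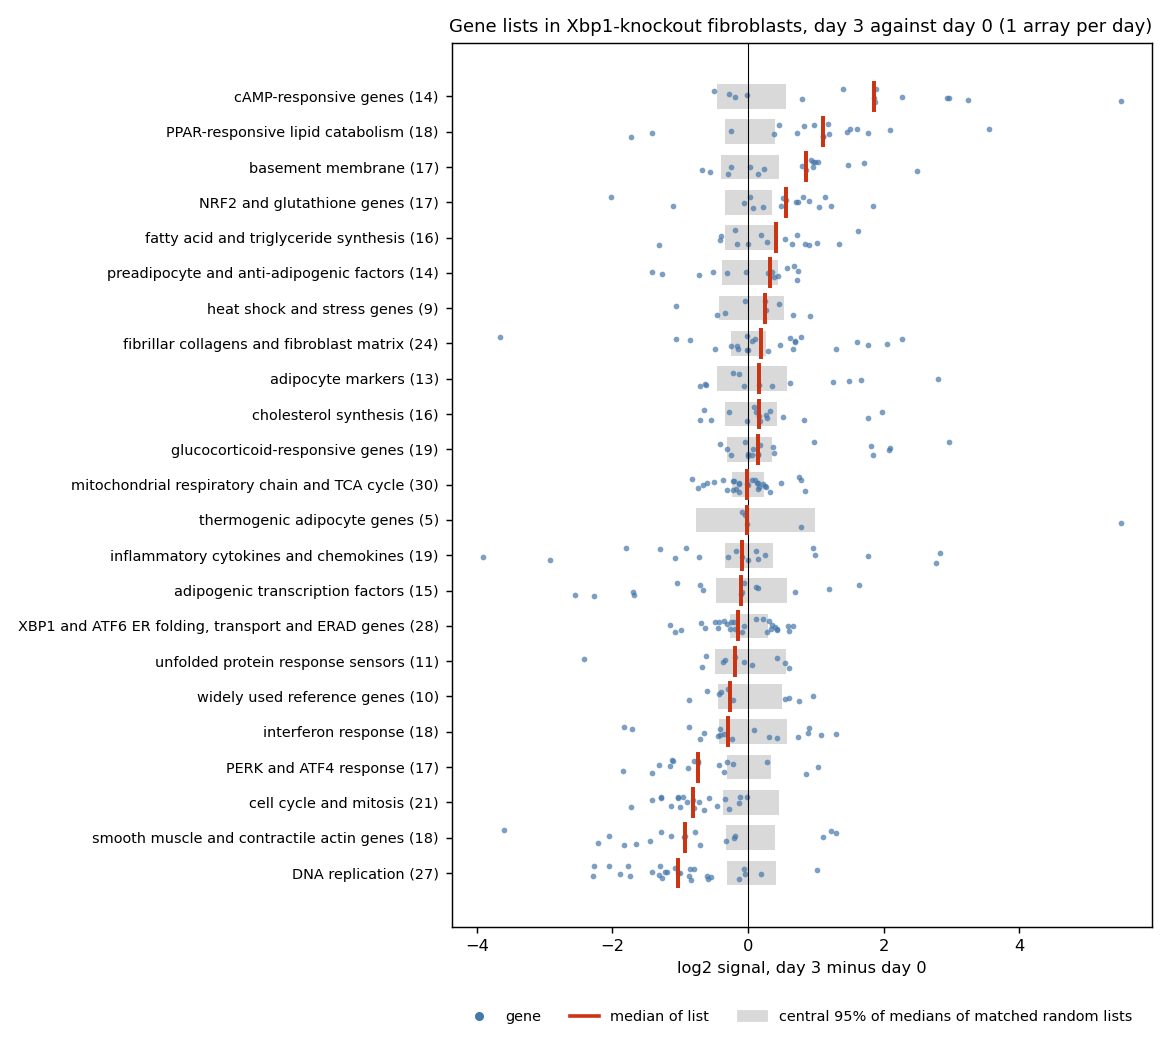
Log2 difference of signal, day 3 minus day 0, for each detected member (points) of the 23 gene lists, with the list median (red line) and the central 95% of medians of matched random lists (grey bar); the number of detected genes stands in parentheses. The medians of cAMP-responsive genes (1.86) and lipid catabolism genes (1.10) lie above their bars and those of DNA replication (-1.03) and contractile genes (-0.94) below.

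The 7 marker sets of other cell types with a median lay inside the matched random range, though neural markers reached percentile 99.2 of lists not matched on signal. The medians were 0.00 for osteoblast (3 detected), -0.73 for chondrocyte (3), 0.76 for muscle (3), 0.35 for macrophage and leukocyte (8), -0.49 for endothelial (5), -0.10 for epithelial (5) and 0.98 for neural markers (6), and of the erythroid markers only Epor was detected (0.79). The osteoblast median is the value of Spp1, which was saturated on both days. With signals under the threshold set to it, the medians were 0.06 for neural, -0.04 for chondrocyte and -0.46 for endothelial markers. Single markers went both ways: Itgam (2.34), Cd14 (1.31) and Tnnc1 (1.69) were higher on day 3, and Csf1r (at least 2.21-fold) and Tubb3 (-1.42) were lower.

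Across all detected genes that met the naming rule, the largest differences toward day 3 were in Csta2 (probe mMC006159), a cystatin-family gene with signals of 677.5 and 22478.5 (33.2-fold), the macrophage receptor gene Vsig4 (20.1-fold), Olfr275 (16.3-fold), the growth factor binding protein gene Igfbp5 (14.7-fold), Stat4 (11.8-fold), the growth factor gene Gdf5 (11.2-fold), the cytokine gene Il11 (10.1-fold), Aoc2 (9.55-fold), Nr4a1 and the alcohol dehydrogenase gene Adh1 (9.33-fold). A further probe gave 3.93 for Igfbp5 (3.88 by the brightest) and 3.62 for Gdf5 (3.48), but -0.34 for Aoc2 (3.26). Olfr275 and Stat4 each had a further probe that stayed below the threshold on both days, so it does not back their differences. The largest differences toward day 0 were in Thbs1, which encodes a matrix glycoprotein, Dio3 (10.97-fold), whose product inactivates thyroid hormone, the chemokine gene Ccl7 (7.59-fold), Tnfrsf11b (7.57-fold), which encodes the decoy receptor osteoprotegerin, Rab32 (7.37-fold), the D-type cyclin gene Ccnd2 (6.53-fold), the pseudouridine synthase gene Pus7 (6.52-fold), Mcpt8 (6.46-fold), Plscr2 (6.40-fold) and Dpysl3 (5.97-fold). The other detected probes of Pus7 gave -1.23 and -1.69. Over the array, 1603 genes had a second probe above the threshold on both days, and of the 315 that were 2-fold by the brightest probe, 83.8% had the same direction and 44.4% were also 2-fold by the second.

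**Figure D3:**
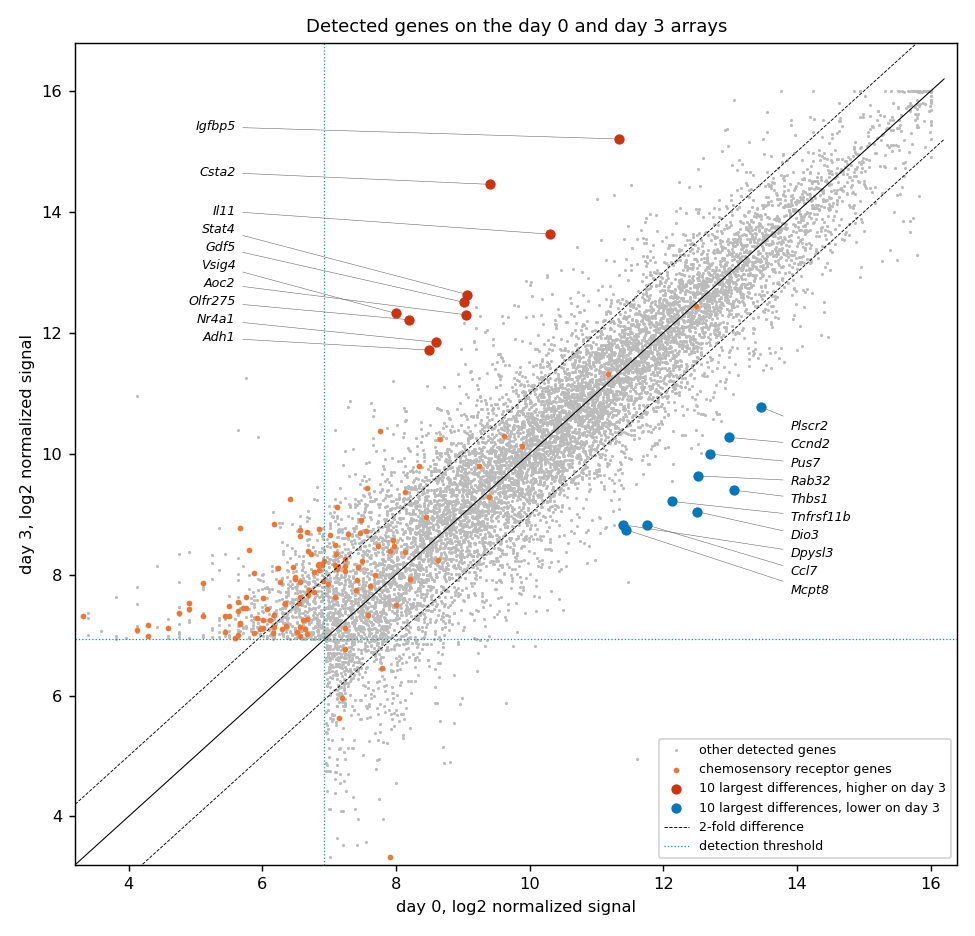
Log2 normalized signal of each of 10656 detected genes on day 0 (horizontal axis) and day 3 (vertical axis), with chemosensory receptor genes in orange and the 10 largest differences of the naming rule in each direction in red and blue. Signals below the threshold are drawn as read. Dashed lines mark 2-fold differences and dotted lines the detection threshold of 6.93, and 78 of the 126 chemosensory receptor genes lie above the upper dashed line.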

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

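The tests of scaling, of the sensitivity of the day 3 array, of named genes against chemosensory receptor genes, and of Fabp4 and Adipoq against probes with the same day 0 signal were chosen after the results were seen.

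Outside the gene probes, the arrays carried 281 control features, 276 of them with 6 spots, whose meaning is not given in the sources used here. Of these, 1 was over 50-fold brighter on day 3 (AM_c_0000019, median raw intensity 12.5 on day 0 and 63385.5 on day 3). The other way, 7 were bright on day 0 and near background on day 3: mCT038126 (65475 and 59.5), mCT038646 (65472 and 17), mCT038366 (35602.5 and 5.5), mCT038629 (65470 and 10.5), mCT038320 (65470.5 and 10.5), mCT038728 (65471 and 10.5) and AM_c_0000022 (65471 and 5). Among the 3173 detected probes with no gene symbol, which enter none of the gene counts, 532 were at least 2-fold higher on day 3 and 362 at least 2-fold lower.

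The first pattern weighed is the 1360 genes at least 2-fold higher on day 3, with an olfactory receptor gene, Olfr275, among the 10 largest differences. Nonspecific signal that differs between the arrays may account for part of the dim end of that count. Chemosensory receptor genes were 2-fold higher 2.924 times as often as other detected genes of the same mean signal (exact binomial 95% interval 2.495 to 3.325). They were 2-fold lower 0.170 times as often (0.047 to 0.425). Because 123 of the 126 detected were dimmer genes, these ratios cannot say whether bright genes are free of such signal. The intervals treat the genes as independent draws and the expected counts as exact. They leave out variation between cultures and hybridizations. Scaling may account for part of the count as well, since it was 829 under median scaling over all gene probes. It was at least 1312 under each normalization once the shift of all genes was removed, but the median scalings and no normalization are then nearly the same setting. For the 10 largest named differences scaling is unlikely to be the whole source. The smallest of them under any of 5 normalizations was 2.725, with no shift removed. Each of the 10 covered the same range of 1.09, because the scalings move all genes alike. The 10 were picked as the largest in the main setting. These values therefore say only that a common shift of that size is too small to produce such differences. Nonspecific signal stays open for them, because the naming rule asks for bright genes and so fixes that 10 of 10 gained more than 420, the upper limit of the central 95% of day 3 signals of chemosensory receptor genes, and a difference in biology, cultures or hybridizations stays open because each day is 1 array.

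The second pattern is that Fabp4 and Adipoq stayed below the threshold on both days, which for Adipoq held in the main setting, under median scaling over all gene probes and under cyclic loess, but not with no normalization or under median scaling over probes detected on both days. The median log2 difference of unnormalized signals of detected genes was 0.669, toward day 3, so a general loss of intensity on the day 3 array is unlikely. Sensitivity for a given gene cannot be judged from this value, because more nonspecific signal on day 3 would raise it as well. Dim probes that carry no signal of their gene stay open: the day 3 signals lay at percentile 98.26 for Fabp4 and 99.84 for Adipoq among probes at the floor on day 0, but both probes were above the floor then (10.5 and 12), and among probes with the same day 0 signal Fabp4 lay at 96.67 (600 probes) and Adipoq at 99.3 (604 probes). Low expression on day 3 and nonspecific signal cannot be told apart for these genes either, because among 391 chemosensory receptor genes as dim on day 0 Fabp4 lay at percentile 95.65, inside their central range, and Adipoq at 99.74, outside it. No biological explanation was tested, since cells with intact Xbp1 were not analysed here.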

How the results depend on the processing

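The floor at the detection threshold, median scaling over probes detected on both days and the filter on mean signal were chosen after the data were seen. Values for genes and lists are relative to the shift of the median of all genes under each setting. The direction of Xbp1 held under all 11 alternatives. Of 1402 comparisons of a named gene with an alternative, 1319 moved by less than the repeat-spot SD, 82 by more, and 1 reversed: Insig1 was -0.060 with the mean of all probes, because its probes disagree. Many of these comparisons, those of Xbp1 included, could hardly move. The detection filters leave a gene's own values as they are, and removing the shift takes out most of what the scalings change. The mean of all probes changes only genes with more than 1 probe. Of 249 comparisons for lists, 202 stayed within 1 SD of random-list medians.

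The number of genes 2-fold higher and 2-fold lower was 829 and 2586 under median scaling over all gene probes, 3939 and 315 with no normalization, 2235 and 1789 with no detection filter, 383 and 371 with both days above the median of detected probes, 814 and 695 in the authors' table, and 437 and 398 with mean signal above the median of detected genes. It was 2570 and 2243 at 1.5-fold and 486 and 411 at 3-fold. The filters, the authors' table and the thresholds change the number of genes counted; for the scalings the cause was not tested beyond the shift of all genes. Adipoq, below the threshold in the main setting, was detected on day 3 with no normalization (10 and 164, threshold 118) and under median scaling over probes detected on both days (10 and 138, threshold 117), and so was Ern1 (69 and 140, then 84.9 and 117.9).

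The median of cAMP-responsive genes turned to -0.013 with both days above the median of detected probes, a filter that by construction removes genes dim on day 0, and was 1.31 with the offset, 1.46 with the mean of all probes, 1.11 with the floor at the threshold and 0.93 with the filter on mean signal. With no normalization the medians were 0.69 for adipocyte markers, 0.19 for fatty acid and triglyceride synthesis, 0.91 for lipid catabolism, -0.95 for the PERK and ATF4 response, -0.038 for glucocorticoid-responsive genes, -0.12 for fibrillar matrix, -1.16 for contractile genes, -0.31 for mitochondrial genes, 0.47 for thermogenic genes, -0.44 for inflammatory genes and -0.26 for heat shock genes. Median scaling over all gene probes gave 0.68 for adipocyte markers, -0.049 for fibrillar matrix, -0.25 for mitochondrial, -0.0016 for interferon response, -0.45 for inflammatory and -0.19 for heat shock genes. Median scaling over probes detected on both days gave 0.72 for adipocyte markers, 0.22 for fatty acid and triglyceride synthesis, -0.92 for the PERK and ATF4 response, -0.086 for fibrillar matrix, -1.13 for contractile, -0.28 for mitochondrial, -0.038 for interferon response, -0.41 for inflammatory and -0.23 for heat shock genes. In the authors' table, adipogenic transcription factors were at -0.55, adipocyte markers at -0.15, fibrillar matrix at 0.061, basement membrane at 0.53, thermogenic genes at 0.80 and interferon response at 0.10. Adipocyte markers were at -0.14 and basement membrane at 0.50 under both filters on brighter genes, and the filter on mean signal gave 0.59 for fatty acid and triglyceride synthesis and 0.053 for fibrillar matrix. The mean of all probes gave 0.59 for fatty acid and triglyceride synthesis, 0.60 for basement membrane and 0.013 for heat shock genes, and without a detection filter preadipocyte factors were at 0.00. The cause of these moves was not tested. The interferon and thermogenic lists had too few detected genes for a median under the filters on brighter genes. With random lists not matched on signal, 2 of the calls changed.

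Signal over background limits what can be said of dim genes: 81.0% of gene probes on day 0 and 89.3% on day 3 exceeded the 95th percentile of empty spots. The 5328 dimmer detected genes held 923 of the 1360 genes 2-fold higher and 695 of the 1093 genes 2-fold lower.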

Other observations

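The 4 gene lists of this part were chosen after the data were seen; the tests of the ribosome biogenesis genes were set before their members' values were looked up.

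Genes of growth factor binding, imprinting and the circadian clock included some of the larger differences without standing apart as lists. Of 16 detected genes of the insulin-like growth factor axis, 4 were 2-fold higher on day 3, 3 of them also with signals under the threshold set to it, and 2 were 2-fold lower (median 0.16, percentile 77.5 of matched random lists), with Igfbp5 (3.88) and the protease gene Pappa (1.44, and 2.15 by its other probe) higher and Htra1 (-1.98) and Igfbp6 (-1.61) lower. Among 17 imprinted genes 2 were 2-fold higher, Mest (2.70) and Nnat (1.01), and 2 were 2-fold lower, Peg3 (-1.45, and -2.51 and -1.83 by its other probes) and H19 (-1.12), with a median of -0.26 at percentile 9.58. Of 14 circadian clock genes 3 were 2-fold higher, including Nfil3 (1.60) and Per1, and 0 were 2-fold lower (median 0.07, percentile 56.7). The iodothyronine deiodinase genes stood at opposite ends: Dio2, which activates thyroid hormone, was at least 19.9-fold higher on day 3 and Dio3, which inactivates it, was 10.97-fold lower.

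The third pattern weighed is that genes of ribosome biogenesis were lower on day 3. Several of them (Nop56, Nop58, Rrp12, Rrp9, Nolc1, Grwd1, Pus7, Trmt61a and Pa2g4, named because they prompted the list) had been seen among the lower genes and were left out of the test, and of 66 other detected members 38 were 2-fold lower, 37 of them also at their bound, 0 were 2-fold higher and 92.4% were lower, among them Noc3l (-2.03), Wdr3 (-1.94), Ltv1 (-1.90) and Polr1b (at least 2.46-fold). A bias between the arrays that follows signal intensity is unlikely to account for it, since the median lay at percentile 0 of random lists matched on mean signal under each of 5 normalizations, 1 of them added after the data were seen, and in the authors' table, the highest percentile being 0.0. No normalization and the median scalings differ by 1 constant per array, which leaves such a percentile almost unchanged, so they repeat 1 check. The authors' table appears quantile normalized, like the main setting. The median of the members tested, -1.096, is in line with lower expression of this group on day 3, and relative to all genes it ranged from -1.23 to -1.06 over these settings. It may go with the lower proliferation genes on the same array, but a difference between the cultures that has nothing to do with induction stays open with 1 array per day.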
